A study of Mus musculus with 2 samples.

How the data were processed

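Droplet single-cell RNA sequencing (10x Chromium 3' chemistry) was done on liver non-parenchymal cells of mice on an MCD diet, with 1 library of the PKM2FL/FL genotype and 1 library of the PKM2ΔMAC genotype. The deposited values are raw UMI counts (unique molecular identifiers, 1 per captured transcript) for each gene and cell barcode, made by the authors with Cell Ranger 6.0.0 per the file headers and with genome build mm10 per the submitters' processing notes. Seurat 4.3.0 is named per the submitters' processing notes, without its use being stated. No barcode held fewer than 502 UMIs, so the barcodes had been filtered before deposition, by a rule that the notes do not state. The number of mice behind each library and the Cre driver are not given in the sources used here.

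Both libraries list the same 27998 genes, of which 18964 had at least 1 UMI. Cells with at least 300 detected genes and under 20% mitochondrial UMIs were kept, which removed 64 barcodes of the PKM2FL/FL library (FL/FL below) and 72 of the PKM2ΔMAC library (ΔMAC below). Doublets were then called in each library with Scrublet in scanpy 1.11.5 at an expected rate of 0.08. This removed 508 FL/FL barcodes (5.09%) and 347 ΔMAC barcodes (3.91%), and left 9482 and 8530 cells with 49604395 and 40316664 UMIs. Free RNA was not subtracted, since empty droplets were not used here. Genes at more than 10 times the level in another class were instead kept out of the ranking of named genes.

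Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen by dispersion within bins of mean level in each library, and 30 principal components were taken. Mitochondrial, ribosomal protein, haemoglobin and Xist genes and 4 Y-linked genes were not used as variable genes. A graph of shared neighbours (20 neighbours per cell) was clustered with leidenalg 0.10.2 at resolution 1, both libraries together and without batch correction, which gave 26 clusters. Each cluster was named from fixed marker lists. A marker counted at 10% of cells or more and at 1.5 times its level in the other clusters, at least 3 markers were needed, and a cluster stayed unnamed where its 10 leading genes held more markers of another class. Class names carry the ending "-like", since they rest on transcripts alone. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.

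Shares of cells carry exact Clopper-Pearson intervals. For expression, UMIs were summed over the cells of a class in each library and divided by the class total in that library, giving CPM (counts scaled to a class total of 1e6) with exact Poisson intervals, and ratios of the ΔMAC library over the FL/FL library with exact conditional intervals. All intervals are at 95% and cover counting error only, not differences between animals or preparations. Where a library had 0 UMIs of a gene, a floor of 3 counts stood in for it and the ratio is a bound. Expression was compared in the 7 classes with at least 100 cells in each library. Gene lists written beforehand were summarised by the median log2 ratio of members with at least 20 UMIs, for lists with at least 3 such members. A member was counted as higher or lower where it lay at least 1.25-fold apart. Each median was placed among 10000 random lists of the same size drawn from genes in the same of 20 bins of level, which describes these 2 libraries and tests nothing between genotypes. Counting intervals of medians came from 500 Poisson draws.

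The rule for naming genes ranked genes with at least 100 UMIs over both libraries and at least 100 CPM in the higher library. It took the 12 highest and 12 lowest log2 ratios in the macrophage class and the 4 highest and 4 lowest in every other compared class. Mitochondrial, ribosomal protein and haemoglobin genes, Xist and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, immunoglobulin and T cell receptor segments, predicted genes named only by a Gm or Rik symbol and markers of other classes were left out of the ranking. Members of gene lists are named from those with at least 50 UMIs, farthest from 0 in the direction of the list's median. Members that went the other way were chosen after their values had been seen. Genes at least 2-fold apart were counted under the same minimums as a matter of size alone. These counts include the genes left out of the ranking. Gene positions were taken from the GENCODE M21 annotation of the same build.

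The filters, resolution, marker lists, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The numbers of variable genes, components and neighbours and the scoring of clusters against markers were set while the clusters were being viewed. The design had pooled Kupffer-like and monocyte-derived macrophage-like cells as the macrophage class. No cluster of the latter kind formed at resolution 1, so Kupffer-like cells stand for that class, and a second clustering of the mononuclear phagocytes alone (12 sub-clusters) was added after the data had been seen. The search for genes that lay apart in every class, with its minimums of 30 UMIs, 3 classes and 1.75-fold and 1 count added to each sum, followed a first look at the data, as did leaving out classes where free RNA could set the value and the study of the X chromosome, of the unnamed cluster and of Lyz2.

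The alternatives were under 10% mitochondrial UMIs, at least 500 genes per cell, doublets kept, resolution 0.5 and resolution 2, each library clustered alone, shares of immune cells only, scaling by the median ratio over genes, the mean over cells of each cell's own CPM, cells thinned to 500 UMIs, list members with at least 100 UMIs, and a minimum of 50 UMIs without a CPM minimum. Sub-clusters of the mononuclear phagocytes, pooled or alone, and clustering without the genes apart in every class were added later. Scaling by the median ratio moves all genes by 0.30 on the log2 scale in neutrophil-like cells, where the median of all genes was -0.30, and by 0.11 in T, NK or innate lymphoid-like cells, where it was -0.11. In the other 5 compared classes the median of all genes lay between -0.09 and 0.00.

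The expression step was run on simulated counts, drawn as independent Poisson counts per gene at the real levels and depths. The known scale of the simulated change, which real data do not give, was added back to the ratios and their intervals. These draws hold no spread between cells or animals and no shared regulation of list members. They therefore check the arithmetic and not the behaviour of real lists. In Kupffer-like cells, simulated over 465 genes, set folds of 1.5, 2 and 4 came back as log2 ratios of 0.57, 1.00 and 2.04, and 95.5% of the 95% intervals held the set value. Of 100 unchanged lists, 4 lay outside the middle 95% of random lists. In classical monocyte-like cells, over 4884 genes, the log2 ratios were 0.61, 1.05 and 2.01, the intervals held the set value for 94.5% of genes, and 2 of 100 unchanged lists lay outside. The comparisons for stellate cells and endothelial cells fixed beforehand were left out, since those classes had fewer than 100 cells in a library. T cell receptor and immunoglobulin segments were not used here as markers, since the marker names for them matched no listed gene.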

Results

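Liver non-parenchymal cells, the immune, endothelial and stromal cells that remain when hepatocytes are removed, were collected from mice after 8 weeks on an MCD diet. That diet lacks methionine and choline and is used to produce a fatty, inflamed and scarring liver. The PKM2FL/FL library (FL/FL) comes from mice with a floxed Pkm gene. The PKM2ΔMAC library (ΔMAC) comes from mice named for a macrophage deletion of PKM2, a pyruvate kinase isoform encoded by Pkm. The series title places the question in macrophages and the fibrosis of steatohepatitis. The FL/FL library held 10054 barcodes with 54519921 UMIs, a median of 4504.5 UMIs and 1708 genes per barcode. The ΔMAC library held 8949 barcodes with 43134027 UMIs, a median of 3791 UMIs and 1491 genes. There were no replicates, with 1 library per genotype, so every difference is a description of these 2 libraries, and no test between genotypes was possible. Intervals in parentheses are 95% intervals and cover counting error only.

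Pkm (ENSMUSG00000032294, chromosome 9, 59656368 to 59679375, mm10), the targeted gene, encodes the pyruvate kinase that completes glycolysis. Its level was lower in the ΔMAC library in 11 of 12 named classes. Kupffer-like cells, the resident liver macrophages, had 309.6 CPM (229.8 to 408) in the FL/FL library and 125 CPM (79.4 to 188) in the ΔMAC library (ratio 0.404, 0.236 to 0.675). Neutrophil-like cells had 755 CPM (716 to 796) against 350.1 CPM (323 to 379) (ratio 0.464, 0.420 to 0.511), where the median of all genes was itself lower, at -0.30 on the log2 scale. Classical monocyte-like cells had 637 CPM (609 to 666) against 328 CPM (298 to 361) (ratio 0.515, 0.463 to 0.572). The lymphocyte classes lay closer together, with a ratio of 0.742 (0.711 to 0.774) in T, NK or innate lymphoid-like cells and 0.835 (0.753 to 0.924) in B-like cells. Ratios were 0.765 (0.685 to 0.854) in conventional dendritic-like cells, 0.737 (0.590 to 0.920) in plasmacytoid dendritic-like cells, 0.563 (0.436 to 0.723) in basophil or mast-like cells (0.355 with each library clustered alone) and 0.511 (0.367 to 0.710) in plasma-like cells. Among stromal classes, endothelial-like cells had 0.662 (0.467 to 0.928), mesothelial-like cells 0.755 (0.509 to 1.11), and the class named stellate or fibroblast-like, led by smooth muscle genes and with the opposite direction, 1.08 (0.595 to 2.08). The latter 2 intervals include equal levels, and endothelial-like cells differed in depth, with a median of 2261 and 976 UMIs per cell in the FL/FL and ΔMAC libraries. The 3' tags of this assay may lie outside the deleted part of Pkm, so these levels do not check the deletion, and Kupffer-like cells rest on 50 and 23 Pkm UMIs.

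**Figure D1:**
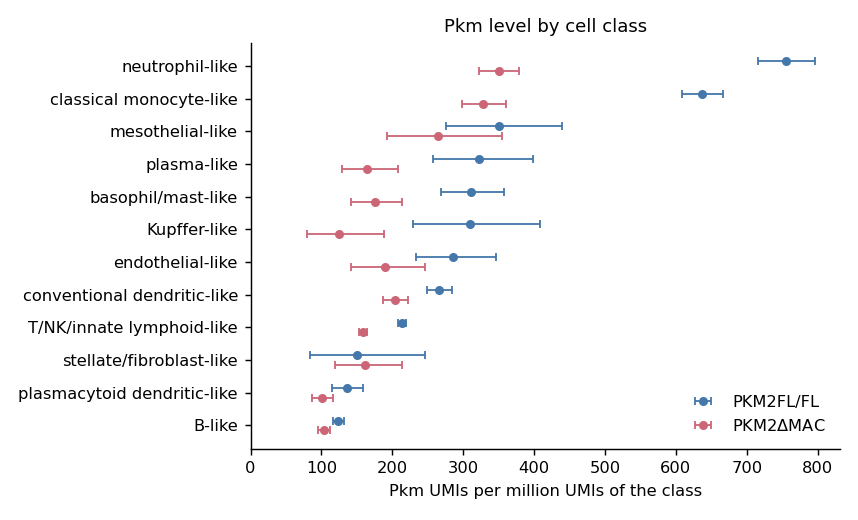
Pkm level in CPM, relative to all UMIs of each class, with 1 point per library and class and 95% Poisson intervals. Kupffer-like cells stand at 309.6 and 125.2 CPM and neutrophil-like cells at 755 and 350.1 CPM in the FL/FL and ΔMAC libraries.

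Cell composition was compared to see which liver immune and stromal cells each library held. T, NK and innate lymphoid-like cells and B-like cells made up most of both libraries, and the ΔMAC library held fewer classical monocyte-like cells and more plasmacytoid dendritic, plasma and stromal cells per 100 cells. Classical monocyte-like cells, led by Chil3, Lyz2, Fn1 and F13a1, made up 3.36% (3.01 to 3.75) against 1.93% (1.65 to 2.25) of cells in the FL/FL and ΔMAC libraries (ratio 0.575, 0.473 to 0.696). Conventional dendritic-like cells, which present antigen to T cells, made up 4.28% (3.88 to 4.71) against 3.36% (2.99 to 3.77) (ratio 0.786, 0.673 to 0.916), of which 95 and 21 cells fell into a low-count sub-cluster, and the ratio was 0.906 when the phagocytes were clustered again. Kupffer-like cells, led by Cd5l, Clec4f and C1qc, were level at 119 and 111 cells (ratio 1.04, 0.793 to 1.35), and so were neutrophil-like cells at 741 and 693 cells (ratio 1.04, 0.936 to 1.15). Plasmacytoid dendritic-like cells, the main interferon-producing cells, made up 1.44% (1.21 to 1.71) against 2.74% (2.41 to 3.11) (ratio 1.90, 1.53 to 2.36), and antibody-secreting plasma-like cells 0.232% (0.145 to 0.351) against 0.563% (0.415 to 0.745) (ratio 2.43, 1.44 to 4.22). B-like cells made up 22.5% (21.6 to 23.3) against 27.8% (26.9 to 28.8) (ratio 1.24, 1.17 to 1.31). Cells that the marker rule named stellate or fibroblast-like, whose leading genes Tagln, Acta2, Myl9 and Myh11 are those of vascular smooth muscle, numbered only 20 and 68 cells (ratio 3.78, 2.27 to 6.57), and mesothelial-like cells 31 and 46 cells (ratio 1.65, 1.02 to 2.69). Endothelial-like cells had 89 and 155 cells (ratio 1.94, 1.48 to 2.54), with a median of 2261 and 976 UMIs per cell, so the cells counted also differed in depth. Basophil or mast-like cells had 81 and 81 cells (ratio 1.11, 0.807 to 1.53), and an unnamed cycling cluster led by Cenpf and Birc5 had 120 and 158 cells (ratio 1.46, 1.15 to 1.87). Shares of 1 preparation per genotype also carry differences in digestion and recovery.

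T, NK or innate lymphoid-like cells made up 51.2% (50.2 to 52.2) against 47.4% (46.4 to 48.5) of cells (ratio 0.926, 0.888 to 0.966), but their make-up differed more than their total. The most numerous cluster of the class in the FL/FL library was NK-like, led by Klra8, Klra4, Gzma and Eomes (1095 and 627 cells, ratio 0.637, 0.576 to 0.703), while another NK-like cluster led by Klra4, Gzma and Klra3 (413 and 352 cells, ratio 0.947, 0.820 to 1.09) and clusters led by Klrb1b and Kit (772 and 680 cells, ratio 0.979, 0.882 to 1.09) and by Cited4 and Klrc1 (250 and 259 cells, ratio 1.15, 0.964 to 1.38) had intervals that include equal shares. In the ΔMAC library it was CD8 T-like, led by Dapl1, Cd8b1 and Lef1, genes of resting T cells (555 and 1033 cells, ratio 2.07, 1.86 to 2.30). A CD8 T-like cluster led by Cd8a, Cd3g and Cd160 was smaller in the ΔMAC library (696 and 340 cells, ratio 0.543, 0.476 to 0.619). Also smaller in the ΔMAC library was a CD4 T-like cluster led by Tnfrsf4, Ctla4 and Cd4, with Foxp3 at 98.9 CPM (336 and 153 cells, ratio 0.506, 0.415 to 0.615). A further CD4-bearing cluster led by Ly6c1 and Pdlim4 (241 and 134 cells, ratio 0.618, 0.497 to 0.767) and a cluster led by the interferon-induced genes Ifit1, Ifit3 and Cxcl10 (170 and 84 cells, ratio 0.549, 0.418 to 0.717) were also smaller there. A cluster led by Cd163l1 and expressing Il23r and Icos, markers of cells that make interleukin 17, was larger (328 and 385 cells, ratio 1.30, 1.12 to 1.52). Among clusters without a class name, the one led by Il4, with Cd40lg, Izumo1r and Cxcr6 next, held 4.19% (3.79 to 4.61) against 0.657% (0.496 to 0.852) of cells (397 and 56 cells, ratio 0.157, 0.116 to 0.208). That cluster carried the T cell genes Cd3d at 752 CPM and Cd3e at 419.6 CPM, stayed unnamed under the marker rule, and was singled out after its values had been seen. It also held Klrb1c at 252 CPM, Tbx21 at 124 CPM and Zbtb16 at 71.9 CPM, with Cd8a at 20.5 CPM and Ncr1 at 8.13 CPM. A small unnamed cluster with bile duct and hepatocyte genes, led by Spp1, Clu and Alb, held 12 and 8 cells.

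**Figure D2:**
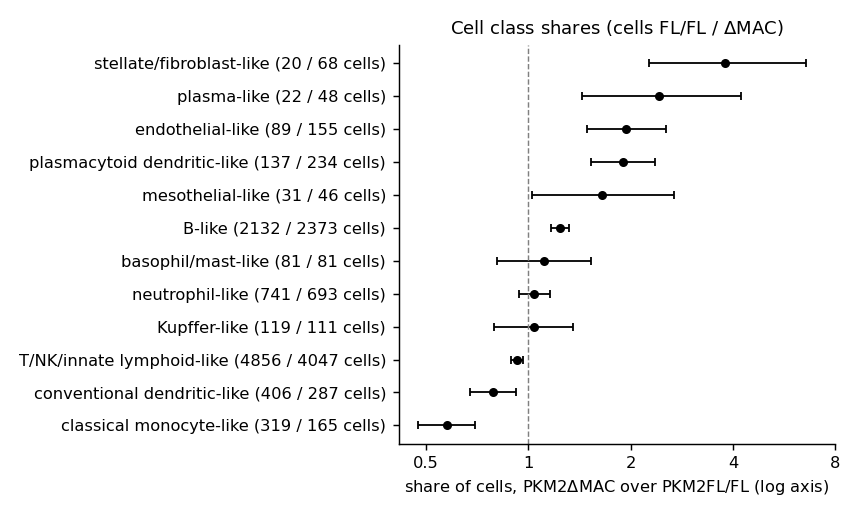
Ratio of the share of all cells in the ΔMAC library over the FL/FL library for 12 named classes on a log axis, with 95% intervals. Classical monocyte-like cells lie lowest at 0.575 and the class named stellate or fibroblast-like, led by smooth muscle genes, highest at 3.78.

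A second clustering of the mononuclear phagocytes alone, added after the data had been seen, separated lipid-associated macrophages from monocytes. A monocyte-derived macrophage-like sub-cluster, led by Gpnmb, Gdf15, Mmp14 and Trem2, genes of macrophages that take up lipid in the diseased liver, held 0.696% (0.539 to 0.885) against 0.129% (0.0644 to 0.231) of cells (66 and 11 cells, ratio 0.185, 0.0882 to 0.353). The larger monocyte-like sub-cluster held 159 and 116 cells (ratio 0.811, 0.633 to 1.04), an interval that includes equal shares. The one with Rsad2 and Cxcl10 among its leading genes held 76 and 38 cells (ratio 0.556, 0.366 to 0.831). Among dendritic sub-clusters, cDC1-like cells, which present antigen to CD8 T cells, had 29 and 61 cells (ratio 2.34, 1.48 to 3.77), and mature dendritic-like cells 46 and 18 cells (ratio 0.435, 0.237 to 0.765). An unnamed sub-cluster with a median of 1120 UMIs, with Gm26917, Lars2, Gm42418 and Malat1 among its leading genes, held 96 and 24 cells (ratio 0.278, 0.170 to 0.438). With the monocyte-derived macrophage-like cells set apart, the ratio of classical monocyte-like shares was 0.729.

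Kupffer-like cells were compared as the macrophage class, which the deletion is named for. Glycolysis genes, mitochondrially encoded genes and antigen presentation genes were lower in the ΔMAC library, while interferon-induced genes were higher. All 11 measured mitochondrially encoded genes counted as lower (median log2 ratio -0.79, percentile 0, from -0.47 under 10% mitochondrial UMIs to -1.58 as the mean of cells' own CPM), among them mt-Nd5 (-0.95) and mt-Nd1 (-0.92), and so did 5 of 7 glycolysis genes (median log2 ratio -0.44, percentile 1.81), led by Gapdh (-0.89) and Aldoa (-0.63). All 6 MHC class II genes, which present antigen to CD4 T cells, counted as lower (median log2 ratio -0.61, percentile 0.22, and -1.34 with at least 500 genes per cell, but 0.31 in the monocyte-derived macrophage-like sub-cluster alone), with H2-Aa (-0.92), Cd74 (-0.82) and H2-DMa (-0.62) lowest. Of 7 MHC class I genes, 5 counted as lower (median log2 ratio -0.40, percentile 2.15), for example H2-K1 (-0.48), a direction that turned to 0.03 when the monocyte-derived macrophage-like sub-cluster was added. Of 12 interferon response genes, 7 counted as higher and 0 as lower (median log2 ratio 0.36, percentile 99.6), with Ifitm3 (0.53), Ifi27l2a (0.37) and Irf7 (0.34). The median was 1.29 with the macrophage-like sub-cluster added and 1.39 in that sub-cluster alone. Its cells came mostly from the classical monocyte-like class (65 and 8 cells, median 11176 and 9627 UMIs, against 992 and 985 in the Kupffer-like sub-cluster). Pooled values thus mix the 2 kinds of cells unequally between the libraries and are not Kupffer-like values. Immediate early genes, which respond to stress and tissue dissociation, had no direction that held, with a median log2 ratio of 0.55 (percentile 100) in the class, 0.0071 as the mean of cells' own CPM, -0.078 in the Kupffer-like sub-cluster alone and -0.79 with the macrophage-like sub-cluster added.

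The other lists in Kupffer-like cells covered lipid handling, inflammation, repair and identity, and most lay within the middle 95% of random lists. Kupffer identity genes lay slightly on the higher side (median log2 ratio 0.14, percentile 97.1), with the complement gene C6 (0.56), the interleukin 18 inhibitor Il18bp (0.45) and the phosphatidylserine receptor Timd4 (0.38) highest. Lipid-associated macrophage genes had a median of -0.20 (percentile 7.29), with the largest gaps in Cd63 (-3.89) and the elastase gene Mmp12 (-1.87). Lipid uptake genes were at -0.29 (4.40) and fatty acid oxidation genes at -0.41 (9.38). Proinflammatory genes went both ways, 6 higher and 7 lower (median log2 ratio -0.14, percentile 27.3), with the endotoxin co-receptor Cd14 (-0.89) and the cytokine Il18 (-0.61) lower and the chemokine Ccl4 (1.82) higher. Ccl5 was at 1.24 in the class but at -0.53 in the Kupffer-like sub-cluster alone, and the class also held a few T, NK or innate lymphoid-like cells (1 and 4), in which Ccl5 is abundant, and B-like cells (5 and 1). Profibrotic genes had a median of -0.26 (12.6), alternative activation genes -0.07 (46.1), matrix degradation genes -0.08 (29.1), efferocytosis genes -0.07 (34.5) and lysosome genes -0.08 (31.8). Metabolic lists beyond glycolysis gave -0.10 for nuclear-encoded oxidative phosphorylation (28.3), -0.30 for the citric acid cycle (13.1) and 0.07 for the hypoxia response (68.9). Erythroid genes, which mark red cell RNA, had a median of -6.83 with 3 of 4 members at their bound, and Hba-a2 had 248 and 1 UMIs (ratio 0.00354, 8.94e-05 to 0.0199). The lists of classical monocyte, neutrophil and hepatocyte genes had fewer than 3 measured members.

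Single genes in Kupffer-like cells were led by lysozyme. Lyz2, an antibacterial enzyme of myeloid cells, had 4848 CPM (4515 to 5200.1) in the FL/FL library and 136 CPM (88.1 to 201) in the ΔMAC library (ratio 0.0281, 0.0181 to 0.0418). The next lowest were Vim, an intermediate filament gene (-1.57), Cxcl13, a chemokine that draws B cells (-1.25), Rsrp1 (-0.97), H2-Aa (-0.92), Gapdh (-0.89), Cd74 (-0.82), Tmem59 (-0.82), Hsp90aa1 (-0.80), Shisa5 (-0.79), Atp5d (-0.76) and Cstb (-0.72), all as log2 ratios. Highest was Maf, a transcription factor of resident macrophages, with 248 CPM (177 to 337) against 631 CPM (522 to 757) (ratio 2.55, 1.77 to 3.75). It was followed by Rgs1, a regulator of chemokine signalling (1.252), Ccl24, a chemokine for eosinophils (1.17), Tmsb4x, an actin-binding peptide (1.07), and the apolipoprotein gene Apoc1 (0.94). The remaining named genes on that side were Klf6 (0.87), Rnaset2b (0.86), Wfdc17 (0.83), Id2 (0.82), Gnb1 (0.81), Uqcr11 (0.79) and Psma6 (0.76). In all, 14 of 465 genes lay at least 2-fold apart, 7 higher and 7 lower, where counting alone would give 0.0447. That count includes genes left out of the ranking, which 362 genes passed. Hba-a2 of red cell RNA is among the 14, so they are not all differences of macrophage genes. Kupffer-like cells were shallow, with a median of 1065 and 1067 UMIs per cell, 0.243 of the library median, and mitochondrially encoded genes also vary with the state of cells after dissociation. The count of genes 2-fold apart came to 240 when the monocyte-derived macrophage-like sub-cluster, with its 66 and 11 cells, was pooled in.

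**Figure D3:**
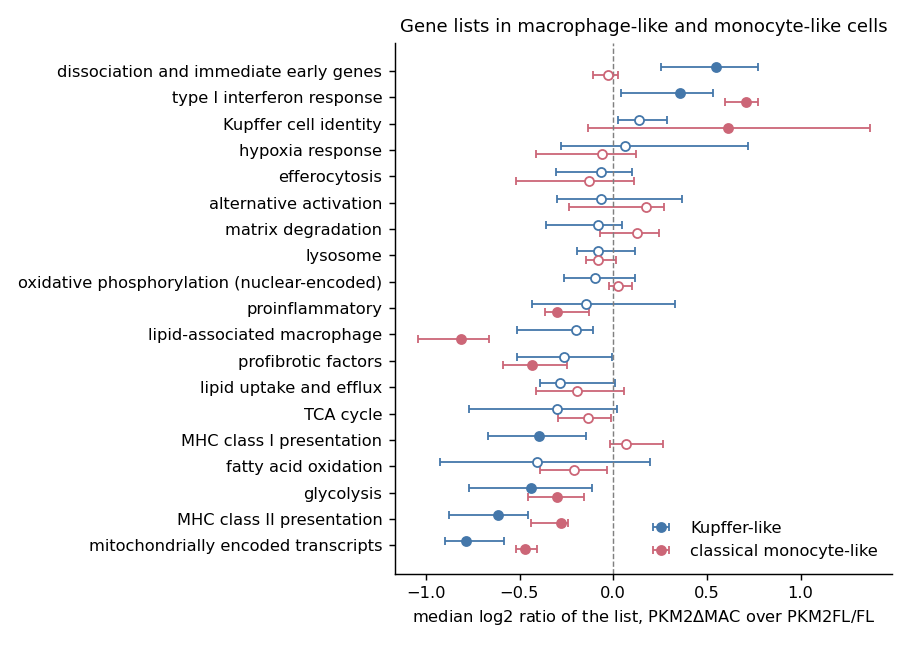
Median log2 ratio of each gene list in Kupffer-like and classical monocyte-like cells, ΔMAC over FL/FL, with 95% counting intervals, where filled points lie outside the middle 95% of random lists. Interferon response genes are on the higher side in both classes (0.36 and 0.71) and mitochondrially encoded genes on the lower side (-0.79 and -0.47).

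Classical monocyte-like cells, the recruited precursors of liver macrophages, were compared for inflammation and metabolism. Interferon-induced genes were higher in the ΔMAC library, while mitochondrially encoded genes were lower, and glycolysis and proinflammatory genes went both ways. Of 19 interferon response genes, 16 counted as higher (median log2 ratio 0.71, percentile 100, and 0.43 in the monocyte-like sub-clusters alone), with Oas1a (1.16), Xaf1 (0.95) and Ifit1 (0.86) highest. Proinflammatory genes were split, 6 higher and 9 lower (median log2 ratio -0.30, percentile 0.01). The neutrophil chemokine Cxcl1 had 288 and 2 UMIs (ratio 0.0160, 0.00192 to 0.0582), and the inflammatory cytokine Tnf (-1.05) and the NF-κB feedback genes Tnfaip3 (-1.22), Nfkbiz (-1.39) and Nfkbia (-1.0) were lower. In the other direction, the chemokines Ccl4 (1.46) and Cxcl10 (1.04), which draw T cells, were higher. The median of that list was -0.07 in the monocyte-like sub-clusters alone and turned to 0.04 when cells were thinned to 500 UMIs. Of 16 glycolysis genes, 7 counted as lower and 4 as higher (median log2 ratio -0.30, percentile 0.29), among them Tpi1 (-0.86), Pfkl (-0.76) and Aldoa (-0.66), while the lactate exporter Slc16a3 was higher (0.53). Mitochondrially encoded genes had 9 of 11 lower (median log2 ratio -0.47, percentile 0.01, but -0.28 in thinned cells and -0.27 as the mean of cells' own CPM), whereas nuclear-encoded oxidative phosphorylation genes lay at 0.03 (percentile 45.3). The citric acid cycle list lay at -0.13 (14.4), fatty acid oxidation at -0.21 (7.83), the hypoxia response at -0.06 (38.7) and immediate early genes at -0.03 (14.8).

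By the naming rule, the lowest genes in classical monocyte-like cells were Lyz2, with 16174 CPM (16032 to 16317) against 18.8 CPM (12.2 to 27.7) (ratio 0.00116, 7.51e-04 to 0.00171), and the chemokine Cxcl3, with 410 and 2 UMIs (ratio 0.0112, 0.00135 to 0.0407). They were followed by Ccl24 (-1.66) and the neutrophil chemokine Cxcl2 (-1.58). The highest were the lysozyme paralog Lyz1, with 43.8 CPM (36.7 to 51.9) against 972 CPM (919.8 to 1027) (ratio 22.2, 18.6 to 26.7), the RNA sensor Tlr7 (1.89), Erdr1 (1.59) and the monocyte chemokine Ccl2 (1.47). Of 1535 genes, 50 lay at least 2-fold apart, 29 higher and 21 lower, again including genes left out of the ranking, which 1366 genes passed. Neutrophil transcripts, listed as possible free RNA, had a median of 0.98 over 19 genes, hepatocyte transcripts -1.97 over 4 and erythroid transcripts -0.38 over 5. Cd177 and Mmp8 of the neutrophil list were among the leading genes of a monocyte-like sub-cluster (159 and 116 cells). The median of the neutrophil list need not measure free RNA in this class. The class pools monocyte-like cells with the FL/FL-rich macrophage-like sub-cluster, and in the monocyte-like sub-clusters alone Ccl24 turned to 1.69, Cxcl3 lay at -0.21 and Ccl2 at 0.83. The Cxcl3 value shows little, since the ΔMAC cells of the class held only 2 of its UMIs. Lyz2, Lyz1, Tlr7, Erdr1 and Cxcl2 kept their direction in those sub-clusters. Of these named genes, 3 left their counting interval in those sub-clusters without turning, and 4 stayed within it.

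Neutrophil-like cells were compared for inflammation and granule genes. Proinflammatory genes were lower and interferon-induced genes higher in the ΔMAC library, against a median of all genes of -0.30. Of 20 proinflammatory genes, 17 counted as lower and 0 as higher (median log2 ratio -0.71, percentile 0, but -0.42 after scaling by the median ratio), with the chemokines Ccl5 (-2.23) and Cxcl1 (-1.44) and the NF-κB feedback gene Tnfaip3 (-1.39) lowest. Cxcl1 lay below 10% of its level in another class, and Ccl5 is abundant in T, NK or innate lymphoid-like cells. Free RNA may therefore set or shift the values of both chemokines. Interferon response genes had 10 of 17 higher (median log2 ratio 0.48, percentile 100, against 0.78 after that scaling and 0.21 with doublets kept), with Ifit1 (1.29), Bst2 (1.08) and Oasl2 (0.79) highest. Granule genes went both ways, with a median of 0.00 (percentile 95), the iron-binding Lcn2 (1.30) and Chil3 (2.35) being higher. The stefin genes Stfa2 (2.13), Stfa1 (1.45) and Stfa2l1 (1.34), with the related BC100530 (1.52), protease inhibitors of young neutrophils, were the 4 highest. The near-identical sequences of this family leave the split of UMIs between its members uncertain. Lowest were Lyz2 with 2507 CPM (2434 to 2581) against 69.1 CPM (57.2 to 82.7) (ratio 0.0276, 0.0228 to 0.0331), the choline kinase Chka (-1.58), Wfdc17 (-1.53) and the kinase Prkd3 (-1.53). Mitochondrially encoded genes had a median of -1.11 (percentile 0), against -0.81 after scaling, -0.68 under 10% mitochondrial UMIs and -0.53 with doublets kept. Nuclear-encoded oxidative phosphorylation genes lay at -0.06 (99.9), which was 0.24 after scaling. Glycolysis genes lay at -0.35 (32.3), citric acid cycle genes at -0.54 (22.4), fatty acid oxidation genes at -0.63 (18.2) and immediate early genes at -0.36 (3.38). The hypoxia list lay at -0.62 (6.16), and at 0.03 over members with at least 100 UMIs. Neutrophil transcripts lay at 0.04 and erythroid transcripts at -1.12, and the hepatocyte list had fewer than 3 measured genes. At resolution 2 the class split into a cluster led by the inflammatory genes Irg1, Slc7a11 and Cxcl2 (258 and 80 cells) and another (483 and 613 cells), so these levels also describe its mixture.

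T, NK and innate lymphoid-like cells were compared for exhaustion, effector and resting-state genes. Genes of chronically stimulated T cells were lower and genes of naive, recirculating T cells higher in the ΔMAC library, against a median of all genes of -0.11. Of 8 exhaustion genes, 6 counted as lower (median log2 ratio -0.57, percentile 0.04, and -0.45 after scaling by the median ratio), with the inhibitory receptors Havcr2 (-2.51), Pdcd1 (-0.93) and Ctla4 (-0.62) and the ectoenzyme gene Entpd1 (-0.73), while Cd160 was higher (0.33). Naive T cell genes had 3 of 7 higher and 0 lower (median log2 ratio 0.32, percentile 100, and 0.43 after that scaling), led by the homing receptors Ccr7 (0.72) and S1pr1 (0.55) and by Il7r (0.40). Cytotoxic genes had a median of -0.17 (percentile 8.02), with Gzmk (-1.53), Prf1 (-0.49) and Gzmb (-0.37) lower. Immediate early genes lay at -0.20 (percentile 0.51), and at -0.085 after that scaling. By the naming rule, Erdr1 (1.76), Tmsb4x (0.90), Nrgn (0.86) and the antiviral deaminase gene Apobec3 (0.84) were highest. The cold-inducible RNA-binding gene Cirbp was lowest, with 219 CPM (214 to 225) against 83.8 CPM (80.0 to 87.7) (ratio 0.382, 0.362 to 0.403), then the signalling adaptor Traf1 (-0.75), Il18rap (-0.70) and Ier5 (-0.63). Lists of free RNA gave -0.22 for hepatocyte, 0.14 for neutrophil and 0.33 for erythroid transcripts. The class mixes clusters whose shares differed between the libraries, so these levels describe its mixture. Among them, the Foxp3-bearing cluster that was smaller in the ΔMAC library has Ctla4 among its leading genes.

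B-like cells were compared for their leading genes and for stress-induced genes. Apobec3, which restricts viruses, had 22.2 CPM (18.8 to 25.9) against 199 CPM (188 to 210.1) (ratio 8.98, 7.59 to 10.7), followed on the higher side by Erdr1 (1.74), the phosphatase gene Ptpn22 (1.13) and Tmsb4x (1.11). Lowest were the NF-κB inhibitor Nfkbia (-0.84), Lrmp (-0.80), the immediate early gene Fosb (-0.78) and the calcium channel gene Itpr2 (-0.76). Immediate early genes as a list lay at -0.21 (percentile 0.215), and at -0.13 in thinned cells. Free RNA lists gave 0.53 for neutrophil, -0.82 for erythroid and -0.45 for hepatocyte transcripts.

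Dendritic-like cells of both kinds were compared for their leading genes. In conventional dendritic-like cells, Fscn1, an actin bundler of mature dendritic cells, was lowest with 177 CPM (163 to 191) against 42.3 CPM (34.7 to 51.1) (ratio 0.239, 0.193 to 0.295), followed by Cacnb3 (-1.89), Tbc1d4 (-1.41) and Cirbp (-1.37). Highest there were Gpr171 (1.64), the metallothionein Mt1 (1.34), the interferon-induced Ifi205 (1.31) and Erdr1 (1.30). Fscn1 and Cacnb3 lead the mature dendritic-like sub-cluster and Ifi205 is among the leading genes of the cDC1-like one, whose shares differed, so these levels describe the mixture. Their immediate early genes lay at 0.28 (percentile 100), with 6 of 17 higher and 0 lower, but at 0.13 in thinned cells and 0.14 as the mean of cells' own CPM. In plasmacytoid dendritic-like cells, Apobec3 was highest with 32.9 CPM (23.1 to 45.3) against 244 CPM (222 to 269) (ratio 7.44, 5.31 to 10.7), then the ubiquitin-like interferon gene Isg15 (2.07), Adam11 (2.06) and Erdr1 (1.96). Lowest were the NF-κB feedback genes Nfkbia (-1.76), Tnfaip3 (-1.60) and Zc3h12a (-1.56) and the sterol synthesis gene Hmgcs1 (-1.62). Immediate early genes lay at -0.10 (9.74) in those cells. Free RNA lists gave 1.63 for neutrophil, 1.55 for erythroid and 0.15 for hepatocyte transcripts in conventional cells, and 0.46 for neutrophil transcripts in plasmacytoid cells, where the other lists of that kind had 2 measured genes each. In conventional cells the hepatocyte list rested on Trf (495 and 412 UMIs), Ass1 and Fabp1, so reading it as free RNA is an assumption.

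Some genes lay apart between the libraries in the same direction in several classes. Of 8734 genes measured in at least 3 of 7 classes, 23 were apart in the same direction in every class measured, 9 higher and 14 lower in the ΔMAC library. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) was lower in all 7, although only Kupffer, classical monocyte and neutrophil-like cells held it at 10% or more of its level in any other class, below which free RNA can set the value. Its neighbour Lyz1 (117287797 to 117292868) was higher in the 3 classes measured, of which only the classical monocyte and conventional dendritic-like ones passed the same limit. The others on the higher side were Apobec3, the stress gene Fkbp5, Erdr1, Tlr7, Igfbp7, Lcn2, Rpgrip1 and Gm5483. On the lower side were the ribosomal RNA-linked Gm42418, the linker histone H1f0, Cdk5rap1, Mtmr9, Irg1, which makes itaconate, Cxcl1, Gpc1, Klhl36, Lrrc32, Zfp503, Rnf135, Slc14a1 and 9930012K11Rik. Without classes below that limit, 13 of the 23 still had at least 3 classes, 3 higher (Apobec3, Fkbp5 and Erdr1) and 10 lower, among them Lyz2, Gm42418 and Cdk5rap1. The remaining 10, among them Lcn2, Irg1, Cxcl1 and Gm5483, are not shown to lie apart beyond 2 classes. The search was set up after these values had been seen, and the free RNA rule was applied to it later.

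Along the X chromosome, 7 measured genes at its distal end, from Tmsb4x at 167207093 to Mid1 at 170005736, were all higher in the ΔMAC library. Their median log2 ratios over classes were 1.03 for Tmsb4x, 1.43 for Tlr7, 1.0 for the nucleotide synthesis gene Prps2, 0.97 for Msl3, 0.82 for Arhgap6, 0.86 for Hccs and 1.05 for Mid1. The median of the 7 was 1.0, a 2.01-fold level, against -0.04 for 280 other X-linked genes and -0.11 for 9192 autosomal genes. Gm15232, ending at 167102090, was the last measured gene before the segment. Among the compared classes the median of the segment ran from 0.60 in neutrophil-like cells, where 2 of 4 genes were above 0, to 1.05 in B-like cells. Among Y-linked genes, Eif2s3y was higher, with log2 ratios of 0.99 in T, NK or innate lymphoid-like cells and 0.86 in B-like cells, while Ddx3y was level there, at 0.00 and 0.02. Erdr1, whose gene ID the annotation places on chromosome Y (90784738 to 90816464), was higher in all 6 classes measured. Xist, transcribed in female cells, had at most 2 UMIs in any class. These genes were chosen after the data had been seen.

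**Figure D4:**
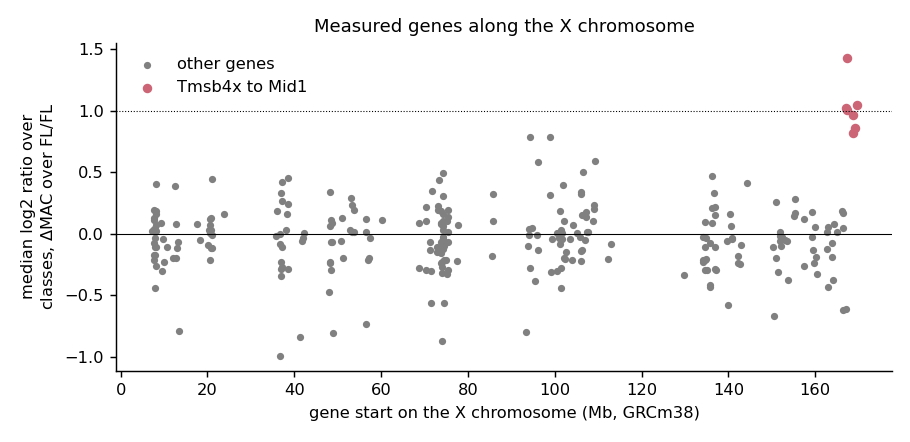
Median log2 ratio over cell classes, ΔMAC over FL/FL, of 287 X-linked genes against position on the X chromosome in Mb, with the segment from Tmsb4x to Mid1 in red and a dotted line at 1. The 7 genes of the segment lie between 0.82 and 1.43.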

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

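Among the settings tried, pooling or separating the sub-clusters of mononuclear phagocytes, clustering without the genes apart in every class, and every setting for lists outside the macrophage class were tests chosen only after the results were seen. A value counts as different where it left the counting interval of the reported value, and for thinned cells where the thinned interval also missed that value. Pkm ratios of 12 classes gave 6 different values and 112 within their intervals, with 0 reversals. Shares of 12 classes gave 3 different and 100 within, 20 macrophage lists 50 different, 7 reversed and 236 within, and 63 lists in other classes 82 different, 10 reversed and 602 within. The 72 named genes gave 54 different, 1 reversed and 697 within. After a first version with many more changed values had been seen, the values printed below were limited to reversals and to lists fixed beforehand that lay outside the middle 95% of random lists and do not measure free RNA.

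The count of Kupffer-like genes at least 2-fold apart, 14 as reported, was 240 with the monocyte-derived macrophage-like sub-cluster pooled in and 38 with at least 50 UMIs and no CPM minimum, and stayed within 1.5 times of 14 under the other 10 settings. Pooling also gave list medians of 0.033 for MHC class I (from -0.40), -0.79 for immediate early genes (from 0.55), -1.04 for mitochondrially encoded genes (from -0.79) and 1.29 for interferon genes (from 0.36). Kupffer-like sub-cluster cells alone gave -0.078 for immediate early and -0.95 for mitochondrially encoded genes. Monocyte-derived macrophage-like cells alone gave 0.38 for MHC class I, 0.31 for MHC class II (from -0.61), -0.27 for immediate early, -0.79 for glycolysis (from -0.44), -0.54 for mitochondrially encoded and 1.39 for interferon genes. The mean of both with equal weight was -0.052, -0.35, -0.12 and 0.65 for MHC class I, MHC class II, immediate early and interferon genes. After that clustering the share ratio of classical monocyte-like cells was 0.729 (from 0.575). The classical monocyte-like sub-clusters alone gave -0.070 for proinflammatory (from -0.30), 0.43 for interferon (from 0.71), -0.39 for mitochondrially encoded (from -0.47), 0.063 for lipid-associated macrophage (from -0.81), 0.56 for MHC class II (from -0.28) and -0.10 for monocyte identity genes (from 0.13), and 1.69 for Ccl24 (from -1.66).

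At resolution 0.5, the Pkm ratio of basophil or mast-like cells was 0.431 (from 0.563), the share ratio of T, NK or innate lymphoid-like cells 0.870 (from 0.926), and their immediate early and naive medians -0.25 (from -0.20) and 0.39 (from 0.32). With at least 500 genes per cell, the basophil Pkm ratio was 0.430, the Kupffer-like MHC class II median -1.34 and the monocyte-like interferon median 0.77 (from 0.71). With doublets kept, the basophil Pkm ratio was 0.434, MHC class II in B-like cells 0.022 (from -0.06), and neutrophil-like mitochondrially encoded, proinflammatory and interferon medians -0.53 (from -1.11), -0.58 (from -0.71) and 0.21 (from 0.48). With each library clustered alone, the basophil Pkm ratio was 0.355, Kupffer-like MHC class II -1.26 and monocyte-like interferon 0.79, while stellate and mesothelial-like cells found no FL/FL cluster. The endothelial share ratio of 1.13 (from 1.94) there is no endothelial value, since its FL/FL cluster was also led by Dcn and Igfbp5 and pools stromal cells. Under 10% mitochondrial UMIs, Kupffer-like MHC class II was -1.17 and mitochondrially encoded genes -0.47, and the latter -0.68 in neutrophil-like cells.

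Scaling by the median ratio gave Pkm ratios of 0.804 (from 0.742) in T, NK or innate lymphoid-like and 0.570 (from 0.464) in neutrophil-like cells. It gave 8.93e-05 for MHC class II and -0.15 for immediate early genes (from -0.21) in B-like cells, -0.45 for exhaustion (from -0.57), -0.085 for immediate early and 0.43 for naive genes in T, NK or innate lymphoid-like cells, and 0.37 for immediate early genes in conventional dendritic-like cells (from 0.28). Neutrophil-like medians became -0.81 for mitochondrially encoded, 0.24 for oxidative phosphorylation (from -0.06), -0.42 for proinflammatory and 0.78 for interferon genes, which follows from the shift of 0.30. The mean of cells' own CPM gave 0.0071 for immediate early and -1.58 for mitochondrially encoded genes in Kupffer-like cells, -0.43 for exhaustion and -0.15 for immediate early genes in T, NK or innate lymphoid-like cells, -0.27 for mitochondrially encoded genes in monocyte-like cells (from -0.47) and 0.14 for immediate early genes in conventional dendritic-like cells. Hypoxia genes in neutrophil-like cells were at 0.032 over members with at least 100 UMIs (from -0.62).

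Thinned to 500 UMIs, a depth that every cell reached, medians were 0.13 for immediate early and -1.44 for mitochondrially encoded genes in Kupffer-like cells, -0.13 for immediate early genes in B-like and 0.13 in conventional dendritic-like cells. Classical monocyte-like cells gave -0.28 for mitochondrially encoded, 0.044 for proinflammatory (from -0.30) and 0.34 for profibrotic genes (from -0.43), and plasmacytoid dendritic-like cells -0.10 for interferon genes (from 1.26). Few UMIs per gene are left at that depth, which limits what thinned lists of small classes can show. For all these differences other than the scaling shift, the cause was not tested. No paired analysis was possible because each genotype has 1 library and no label pairs them.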

Other observations

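Tests chosen only after the results were seen were the Lyz1 comparison, the shuffles of genes over positions, Xist, the interferon comparison, both tests on the cluster led by Il4, and the lists added in classical monocyte-like, lymphoid and dendritic-like cells. The tests on the neighbours of Lyz2 and on held cell classes were written before their values were seen, though the patterns came from the same 2 libraries.

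In classical monocyte-like cells, further lists described lipid-associated and profibrotic macrophage genes. Of 14 lipid-associated macrophage genes, 11 counted as lower and 0 as higher in the ΔMAC library (median log2 ratio -0.81, percentile 0), with Gpnmb (-3.79), Cd63 (-2.87) and the elastase gene Mmp12 (-1.91) lowest. The median was 0.063 in the monocyte-like sub-clusters alone, so it depends on which cells of the class are counted. Those sub-clusters leave out the macrophage-like sub-cluster (65 and 8 cells of the class). They also leave out T, NK or innate lymphoid-like (11 and 1), B-like (10 and 6) and a few other cells, and the part of each was not tested. Of 12 profibrotic genes, 7 counted as lower and 2 as higher (median log2 ratio -0.43, percentile 0.04), with the growth factor Areg on 116 and 3 UMIs (ratio 0.0594, 0.0121 to 0.178), Igf1 (-2.35) and Pdgfb (-1.66) lower and Thbs1 higher (0.64), though the median was -0.07 in the monocyte-like sub-clusters alone and 0.34 in cells thinned to 500 UMIs. Medians were -0.28 for MHC class II (0.56 in those sub-clusters alone), 0.07 for MHC class I, -0.19 for lipid uptake (0.12 there), 0.18 for alternative activation, 0.13 for matrix degradation, -0.13 for efferocytosis (0.14 there) and -0.08 for lysosome genes (0.09 there). Identity genes lay at 0.62 for Kupffer cells and 0.13 for classical monocytes (-0.10 there). In plasmacytoid dendritic-like cells, 15 of 17 interferon response genes counted as higher (median log2 ratio 1.26, percentile 100, but -0.10 in thinned cells), while the list lay at -0.28 in T, NK or innate lymphoid-like, -0.12 in B-like and 0.05 in conventional dendritic-like cells. MHC class II genes lay at -0.06, 0.13 and -0.05 in B-like, conventional and plasmacytoid dendritic-like cells. Glycolysis genes lay at -0.18, -0.04, -0.16 and 0.15 in T, NK or innate lymphoid-like, B-like, conventional and plasmacytoid dendritic-like cells.

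Lyz2 was nearly absent from the ΔMAC library, with 49465 and 25 UMIs in classical monocyte-like cells. UMIs assigned to the paralog Lyz1 instead are argued against, since the gain of Lyz1 made up 5.75% of the Lyz2 CPM lost in those cells. A candidate explanation is a change of the Lyz2 locus itself, such as a Cre gene inserted there, which the labels do not state. With Lyz2 and Lyz1 left out, the 10 measured genes within 1 Mb had a median log2 ratio of -0.26, within 0.5 of the -0.02 of all genes. They were widely scattered, from -0.89 to 1.05, and the neighbour Lyz1 was itself higher (ratio 22.2). Level neighbours would also be seen if Lyz2 alone responded to the genotype, so this median cannot tell these explanations apart. A response of Lyz2 and Lyz1 to the genotype in these cells stays open and untested.

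Genes at the distal end of the X chromosome were near a doubled level in the ΔMAC library. Female cells are argued against, since Xist stood at 0.0744 CPM over all cells of that library, on 3 UMIs. Responses of single genes unrelated to their place are argued against, since no run of 7 genes reached the segment's 1.0 when the genes' values were shuffled over all positions (share 1e-04 of 10000 shuffles, the smallest they can give), although the highest of 9359 other actual runs, at 0.55, lay above the 50% of the segment set as a first bound. Differences tied to the place cannot be told apart, among them an additional copy of the segment and a regulation shared by neighbours. Of the classes not used to find the segment, only basophil or mast-like cells had the 5 measured genes that the test required, with a median of 1.23. The others had fewer genes and lower medians, at 1.11 in stellate or fibroblast-like, 0.94 in endothelial-like, 0.77 in plasma-like and 0.68 in mesothelial-like cells. Genes picked for being higher would be higher in such classes under any of these differences. Whether the segment, which holds the RNA sensor Tlr7, or the macrophage genotype goes with the higher interferon genes (0.71 in classical monocyte-like cells) cannot be told apart, because both differ between the same 2 libraries.

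The unnamed cluster led by Il4, with T cell genes, held 397 FL/FL and 56 ΔMAC cells. A split caused by genes that lay apart in every class measured is argued against, since the cluster formed again without those genes, at a share ratio of 0.159. Whether such cells lie in other lymphoid clusters of the ΔMAC library cannot be told apart from their scarcity. Il4 over all these lymphoid cells had 313 and 39 UMIs, a ratio of 0.165 (0.115 to 0.231), but it leads the cluster and so was picked by the pattern. A lower yield in 1 preparation and a difference that goes with the genotype both stay open.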
